A study of Homo sapiens with 12 samples.

How the data were processed

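Gene expression was measured in Caco-2 cells, a human colon carcinoma line that serves as a model of intestinal epithelium. There were 4 groups of 3 RNA samples each, with 1 array per sample and 12 arrays in all. Clones selected with blasticidin (1 µg/ml) stably overexpressed HA-tagged TLR4, either the wild type (TLR4-WT) or one of the mutants TLR4-D299G and TLR4-T399I, after transfection with 1 µg of plasmid per well. The controls were untransfected cells that had received no exogenous DNA, and no empty-vector line was among the groups. Cells grew for 8 days before RNA was taken, and biotin-marked target was hybridised to Affymetrix whole-transcript arrays. The labels do not say whether the 3 samples of a group came from separate cultures or clones. P-values therefore measure only the spread between these samples, which may be technical.

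Per the submitters' processing notes, the authors summarised the arrays with Affymetrix Expression Console 1.0 and RMA, a method that corrects background, normalises by quantiles and summarises probes. The deposited values are log2 expression values, given to 2 decimals, for 33297 probe sets on each array, with 0 missing and no detection calls. Array medians ran from 6.88 to 6.97, lower quartiles from 5.2 to 5.29 and upper quartiles from 8.71 to 8.85. The number of arrays limits the precision. The values were used as deposited, with no further normalisation and no filter on low values.

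The deposited probe annotation gave exactly 1 gene symbol for 19460 probe sets, several for 1754 and none for 12083. Of the first kind, 19429 matched a gene name in the RefSeq annotation of assembly GRCh38, and 0 symbols needed an update. That annotation was used for names and for the order of neighbouring genes only, since the genome build of the array was not named. For gene lists and named genes, the probe set with the highest mean over the 12 arrays stood for its gene, which gave 18417 genes, of which 769 had more than 1 probe set. Among called probe sets, 5278 had no single symbol and are counted but not named.

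Differences between groups were tested with limma 3.58.1 in R 4.3.3. A model of group means was fitted to all 12 arrays (8 residual degrees of freedom), followed by empirical Bayes moderation without trend or robust prior. The 6 pairwise comparisons and the mean of the 3 TLR4 lines against untransfected cells were each adjusted by Benjamini-Hochberg over all probe sets, two-sided. A probe set was called at an adjusted p under 0.05. A moderated F test asked for any difference among the 4 groups. A probe set was set apart in a group when it was called with the same sign against each of the other 3 groups. Fold changes are differences of group means on the log2 scale, and errors are the standard error (SE) of the fit or the standard deviation (SD) of 3 arrays. On simulated data with known changes in the D299G against WT comparison, the test recovered 44.8% of 67 probe sets changed by 0.5 on the log2 scale. It recovered 88.1% of 67 at 1 and 98.5% of 66 at 2, with 12 false calls among 33297 probe sets. Far fewer probe sets were changed there than were called in the data, and the adjustment depends on that number, so these rates do not carry over.

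The 23 gene lists covered the TLR4 receptor complex and signalling, NF-kB targets, type I interferon-stimulated genes, MHC class I antigen presentation, and the STAT3 pathway and its targets. They also covered epithelial junctions and keratins, mesenchymal transition, laminins, integrins and matrix remodelling, enterocyte differentiation and brush border, lipoproteins and lipid absorption, and liver secretory proteins. The remaining lists were Wnt targets and intestinal stem cells, proliferation, apoptosis and p53 targets, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein and amino acid stress responses, metallothioneins, and drug metabolism and NRF2 targets. Markers of goblet and Paneth cells, enteroendocrine cells, fibroblasts and leukocytes completed the set. Each list was tested against all other genes with camera from limma, at a preset correlation between genes of 0.01, and adjusted over all 161 tests. Each list was also tested with an estimated correlation and with fry, which asks only whether the genes of a list move one way on balance. List members without a probe set of their own were not analysed here.

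Groups, comparisons, lists, tests, most alternatives and the rule for naming genes were fixed before the data were examined. For the comparisons of TLR4-WT with untransfected cells and among the lines, the rule took the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap. For each mutant line against untransfected cells it took 5 and 5. For genes set apart in a group it took the 8 and 8 with the largest smallest change. It added TLR4 and up to 4 called members of each called list, and left small RNAs, unnamed loci and large near-identical families out of the ranks. The count of probe sets with the same sign in both mutant lines against TLR4-WT was added after the values were seen, with all its alternatives.

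Alternatives were a variance trend with a robust prior, only probe sets at or above the overall median on 3 arrays, only probe sets with 1 symbol, arrays centred on their median, quantile normalisation repeated, array weights, fits on the compared arrays alone, a replicate block, a change of at least 2-fold, an adjusted p under 0.01, and leaving out each array in turn. Lists were also tested on ranks, on the brighter genes and on the mean of a gene's probe sets. For comparisons that share a control group, 20 simulations of unchanged groups gave the correlation that shared arrays alone produce, and the overlap of independent lists was computed. The samples were also split at random into groups of the same sizes, with 100 splits where more were possible. Neighbouring genes were tested in blocks of 50 along the chromosomes against 100 random gene orders. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.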

Results

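TLR4, the receptor for bacterial lipopolysaccharide and the gene carried by the plasmids, had a log2 value of 4.83 ± 0.27 (SD, n = 3) in untransfected Caco-2 cells, below the lower quartile of every array. It reached 8.61 ± 0.11 in the TLR4-WT line, 8.81 ± 0.08 in the TLR4-D299G line and 8.34 ± 0.05 in the TLR4-T399I line. TLR4 was thus at least 13.7-fold, 15.8-fold and 11.4-fold higher than in untransfected cells, and 13.5-fold higher in the mean of the 3 lines (log2 change 3.76, SE 0.10, adjusted p = 2.29e-09). TLR4 in either mutant line did not pass the test against TLR4-WT (adjusted p = 0.328 for D299G and 0.21 for T399I). Between the mutants TLR4 was 1.39-fold higher in D299G (adjusted p = 0.0214), a difference that missed the threshold without D299G replicate 1 or 2 or T399I replicate 1 or 3 (adjusted p from 0.0581 to 0.0833). LY96, which encodes the co-receptor MD-2, lay between 3.46 and 3.69 in all 4 groups, and CD14, which hands lipopolysaccharide to TLR4, between 7.48 and 7.73. The array resolves neither the HA tag nor the D299G and T399I substitutions.

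Untransfected cells and TLR4-D299G stood clear of the other groups across all probe sets, and TLR4-WT and T399I lay closest together. Principal component 1 (37.4% of the variance) parted untransfected cells from the 3 TLR4 lines, and component 2 (18.3%) parted TLR4-D299G from the other lines. Arrays of one group correlated at 0.9902 to 0.9959 across probe sets, arrays of different TLR4 lines at 0.9872 to 0.9925, and untransfected arrays with TLR4 lines at 0.9769 to 0.9855. T399I replicate 1 correlated better with WT replicate 3 (0.9925) than with T399I replicate 2 (0.9918). Any difference among the groups was called at 13962 of 33297 probe sets by limma's moderated F test. Over all probe sets, the values of the 2 groups of a pairwise comparison did not overlap in 26.6 to 47.3%, where chance gives 10%. All genes named below as changed in a pairwise comparison had no overlap between its 2 groups of 3 arrays. Where a gene lay below the lower quartile of the arrays in one group, as TLR4 and NTS did in untransfected cells, SULT1C4 in WT, SI and HEPACAM2 in D299G and SLCO1B3 in every group but D299G, its folds against that group are lower bounds, since the level of background is not known.

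**Figure D1:**
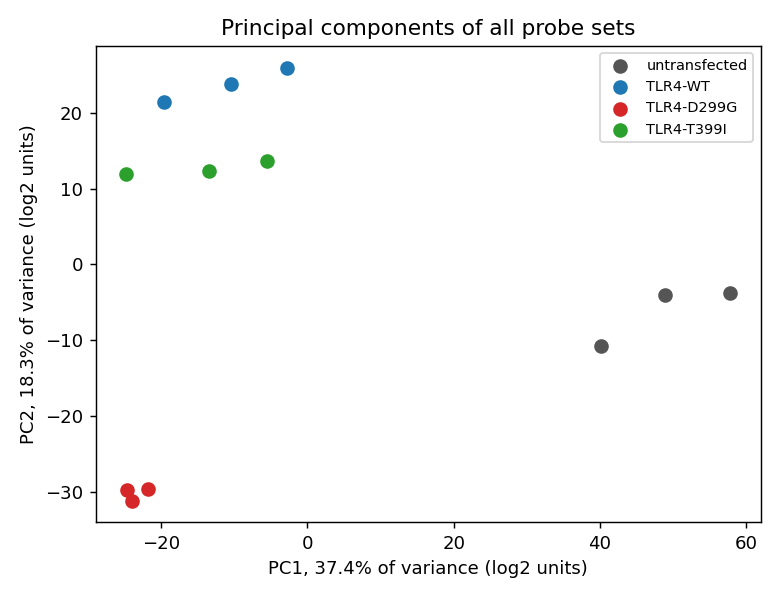
Each point is 1 of the 12 arrays, placed on principal components 1 and 2 (log2 units) of all probe sets and coloured by group. Untransfected arrays lie to the right on component 1, which holds 37.4% of the variance, and TLR4-D299G arrays lie lowest on component 2, which holds 18.3%.

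LGR5 and MYC rose in all 3 TLR4 lines against untransfected cells. LGR5, a receptor of intestinal stem cells, had a log2 value of 8.87 ± 0.08 (SD, n = 3) in untransfected cells and 11.1, 10.71 and 10.52 in TLR4-WT, D299G and T399I. MYC, a Wnt target that drives growth, rose 3.20-fold over the lines (SE 0.05 on the log2 scale, adjusted p = 5.04e-09). NOX1, which encodes the colonic superoxide-producing oxidase, rose 5.72-fold, 13.9-fold and 4.24-fold in the same order, and GPX2, an intestinal glutathione peroxidase, rose 6.25-fold, 5-fold and 10.6-fold. DUSP6, a phosphatase that acts on ERK, rose 3.90-fold or more in each line, and SAMD5 and BST2 also rose in each. HEPACAM2, an adhesion protein of secretory cells, fell 12.0-fold, 23.8-fold and 8.94-fold. C2, a complement component whose probe set has copies on alternative haplotypes, fell 5.19-fold to 8.98-fold, and TSPAN7, OSBPL6, ABCA5, ZNF558, SLC10A5 and EML6 also fell in every line.

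VLDLR, DNAJC3, EDEM1 and SEL1L fell 2.96-fold, 2.34-fold, 1.98-fold and 1.94-fold in the mean of the lines. Their list, unfolded protein and amino acid stress genes, was lower in the mean of the lines (2 of 29 members higher and 18 lower, or 2 and 19 adjusted over the list alone, adjusted p = 5.29e-06, and adjusted p = 0.11 with an estimated correlation). Wnt target and stem cell genes were higher (13 of 25 higher and 5 lower, the same counts adjusted over the list alone, adjusted p = 0.0217, and adjusted p = 0.262 with an estimated correlation). Metallothioneins, small metal-binding proteins with near-identical sequences, were higher (7 of 8 higher, 8 adjusted over the list alone, adjusted p = 0.000185, and adjusted p = 0.184 with an estimated correlation), MT1X by 2.85-fold. That rise came from the mutants, since metallothioneins did not pass in TLR4-WT (4 of 8 higher and 2 lower, adjusted p = 0.79). Liver secretory proteins were lower (3 of 27 higher and 21 lower, the same adjusted over the list alone, adjusted p = 1.96e-09, and adjusted p = 0.262 with an estimated correlation). KNG1 fell 4.55-fold and HPX 4.92-fold in the mean of the lines. The fall of HPX came mostly from WT (7.32 to 7.47) and T399I (6.6 to 6.92), with 9.6 to 9.91 in D299G and 10.13 to 10.48 in untransfected cells. The fall of ALB in that mean (4.16-fold) came from WT and T399I, since ALB in D299G cells overlapped untransfected cells. In D299G alone the liver secretory list did not pass (adjusted p = 0.973). Enterocyte and brush border genes were lower (7 of 35 higher and 18 lower, the same adjusted over the list alone, adjusted p = 0.0173, and adjusted p = 0.455 with an estimated correlation). The peptide transporter SLC15A1 fell 3.79-fold and TM4SF4 2.93-fold, but of the single lines the list passed only in D299G (adjusted p = 0.135 in WT and 0.201 in T399I). MHC class I genes were lower (2 of 14 higher and 7 lower, the same adjusted over the list alone, adjusted p = 0.0492, and adjusted p = 0.452 with an estimated correlation). ERAP1, TAPBP and CALR fell and NLRC5 rose. All 6 of these calls were lost with an estimated correlation. The MHC class I call was also lost without WT replicate 2, D299G replicate 1 or 2, T399I replicate 1 or 2, or untransfected replicate 2 (adjusted p from 0.0535 to 0.0913). It was lost too on ranks (0.0557), among brighter genes (0.09) and with a replicate block (0.058). Ranks ended the enterocyte call (0.0715) and the Wnt call (0.0513), brighter genes the enterocyte call (0.0983), and 12 of 100 splits of the samples gave at least 6 lists.

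Over all probe sets, 13064 were called between the mean of the 3 TLR4 lines and untransfected cells (6773 higher and 6291 lower), of which 594 changed at least 2-fold (134 higher and 460 lower). With arrays centred on their median the split was 5363 higher and 6836 lower. LGR5, MYC and HEPACAM2 were among 5238 probe sets called with the same sign in each line (2463 higher and 2775 lower, or 1853 and 2913 with arrays centred). Independent lists of these sizes would share 137 and 134. Because the comparisons share the untransfected arrays, their changes correlate even without an effect. Across probe sets r was 0.70 to 0.79 against 0.50 in simulation, and the covariance was 0.112 to 0.122 against 0.0101. With 3 control arrays no separate controls could be set aside for each comparison, so part of the excess overlap may come from shared controls.

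In the TLR4-WT line against untransfected cells, the acute-phase protein ORM1 (α1-acid glycoprotein) fell 17.3-fold, from 10.57 ± 0.14 to 6.45 ± 0.13 (SD, n = 3, adjusted p = 9.67e-09). Its near-identical neighbour ORM2, which shares probes with it, fell 15.2-fold. ALB (albumin), HPX (hemopexin), APOH and ITIH2 fell 7.45-fold, 7.50-fold, 5.46-fold and 5.13-fold, and the liver secretory list fell (0 of 27 higher and 23 lower, or 24 lower adjusted over the list alone, adjusted p = 7.23e-15, and adjusted p = 0.158 with an estimated correlation). The sulfotransferase SULT1C4 fell 21.4-fold, the adhesion molecule ALCAM 9.40-fold, the complement protease C1S 7.52-fold and CPE 6.95-fold. LYZ (lysozyme, made by Paneth cells) rose 6.60-fold, and CCSER1, CP and PDE10A rose 4.04-fold to 4.11-fold.

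Wnt target and stem cell genes rose in TLR4-WT, with LGR5 up 4.70-fold, MYC 3.73-fold, ETS2 2.27-fold and SOX4 1.87-fold (12 of 25 higher and 4 lower, or 12 and 5 adjusted over the list alone, adjusted p = 0.0188, and adjusted p = 0.244 with an estimated correlation). The glucose transporter SLC2A1 rose 2.63-fold and HK2 2.22-fold, and the hypoxia and glycolysis list rose (13 of 32 higher and 4 lower, or 14 and 4 adjusted over the list alone, adjusted p = 0.0127, and adjusted p = 0.464 with an estimated correlation). Interferon-stimulated genes fell as a list (6 of 33 higher and 14 lower, the same adjusted over the list alone, adjusted p = 0.0188, and adjusted p = 0.278 with an estimated correlation). IFIT1 fell 4.01-fold, EPSTI1 3.17-fold and IFI6 2.93-fold, while BST2 rose 3.06-fold. Antigen presentation genes fell (2 of 14 higher and 7 lower, the same adjusted over the list alone, adjusted p = 0.0217, and adjusted p = 0.396 with an estimated correlation), led by ERAP2 at 2.08-fold. Unfolded protein and amino acid stress genes fell (1 of 29 higher and 19 lower, or 3 and 19 adjusted over the list alone, adjusted p = 2.16e-06, and adjusted p = 0.11 with an estimated correlation). On ranks the interferon and Wnt calls were lost (adjusted p = 0.0525 and 0.0803), and among brighter genes the interferon call (0.0835). In total 10404 probe sets were called, 5370 higher and 5034 lower (51.6% higher), and 659 changed at least 2-fold (144 higher and 515 lower). With arrays centred on their median the split was 3690 higher and 5656 lower (39.5% higher), so the balance of directions depends on the scaling.

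In the TLR4-D299G line against untransfected cells, sucrase-isomaltase (SI), a sugar-digesting enzyme of the enterocyte brush border, fell at least 71.5-fold, from 10.86 ± 0.02 to 4.70 ± 0.10 (SD, n = 3, adjusted p = 1.59e-10). The gap junction gene GJA1 rose 18.3-fold, the protease inhibitor A2M 13.8-fold and the long non-coding RNA UCA1 12.1-fold. The mitochondrial urea cycle enzyme CPS1 fell 6.85-fold and SULT1C4 9.54-fold. Enterocyte genes fell as a list (4 of 35 higher and 21 lower, or 5 and 23 adjusted over the list alone, adjusted p = 5.19e-05, and adjusted p = 0.242 with an estimated correlation), although the glucose transporter SLC2A2 rose 3.60-fold. Metallothioneins rose (8 of 8, the same adjusted over the list alone, adjusted p = 5.87e-07, and adjusted p = 0.126 with an estimated correlation), MT1X by 5.44-fold, while the 3 probe sets of MT2A gave log2 changes of 1.77, 1.64 and 3.82. The mesenchymal markers VIM and S100A4 rose 3.51-fold and 2.24-fold, and their list rose (13 of 31 higher and 4 lower, or 14 and 4 adjusted over the list alone, adjusted p = 0.0136, and adjusted p = 0.284 with an estimated correlation). Wnt target genes rose (13 of 25 higher and 3 lower, or 14 and 3 adjusted over the list alone, adjusted p = 0.0181, and adjusted p = 0.242 with an estimated correlation), among them the antagonist DKK1 at 2.20-fold. Unfolded protein and amino acid stress genes fell (3 of 29 higher and 15 lower, the same adjusted over the list alone, adjusted p = 0.000601, and adjusted p = 0.158 with an estimated correlation), ASNS by 1.80-fold. Liver secretory genes did not move as a list (11 of 27 higher and 10 lower, adjusted p = 0.973), with ALB at 13.25 ± 0.04 and 13.21 ± 0.06 in D299G and untransfected cells. In total 11785 probe sets were called (5813 higher and 5972 lower), of which 1009 changed at least 2-fold (272 higher and 737 lower), and with arrays centred on their median 4511 were higher and 6531 lower.

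In the TLR4-T399I line against untransfected cells, the cystatin CST1 rose 15.5-fold, from 6 ± 0.27 to 9.95 ± 0.27 (SD, n = 3, adjusted p = 2.5e-07). The gut peptide neurotensin (NTS) rose 13.8-fold, and CLDN6, a tight-junction protein of embryonic epithelium, rose 12.3-fold. ORM1 fell 13.5-fold, HPX 11.4-fold and ALB 9.96-fold, and liver secretory genes fell as a list (2 of 27 higher and 24 lower, the same adjusted over the list alone, adjusted p = 1.8e-17, and adjusted p = 0.14 with an estimated correlation). Lipoprotein and lipid absorption genes fell (4 of 24 higher and 13 lower, the same adjusted over the list alone, adjusted p = 0.000919, and adjusted p = 0.181 with an estimated correlation). ABCA1 fell 4.52-fold and APOC3 4.11-fold, while MTTP rose 3.59-fold. Proliferation genes rose (28 of 40 higher and 1 lower, or 29 and 1 adjusted over the list alone, adjusted p = 1.82e-06, and adjusted p = 0.455 with an estimated correlation). PLK1 rose 1.68-fold and CDC20 and MCM7 1.65-fold. Wnt target and stem cell genes did not pass as a list (10 of 25 higher and 3 lower, adjusted p = 0.0631), except without T399I replicate 1 (0.0287). Metallothioneins rose (7 of 8, the same adjusted over the list alone, adjusted p = 0.000132, and adjusted p = 0.181 with an estimated correlation). STAT3 pathway genes fell (2 of 21 higher and 11 lower, the same adjusted over the list alone, adjusted p = 0.0185, and adjusted p = 0.154 with an estimated correlation), SERPINA3 by 2.23-fold. Unfolded protein and amino acid stress genes fell (1 of 29 higher and 15 lower, or 2 and 15 adjusted over the list alone, adjusted p = 6.32e-06, and adjusted p = 0.11 with an estimated correlation), HERPUD1 by 2.09-fold. In total 9806 probe sets were called (4864 higher and 4942 lower), of which 763 changed at least 2-fold (206 higher and 557 lower), and 6508 were called in a fit of the compared arrays alone.

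**Figure D2:**
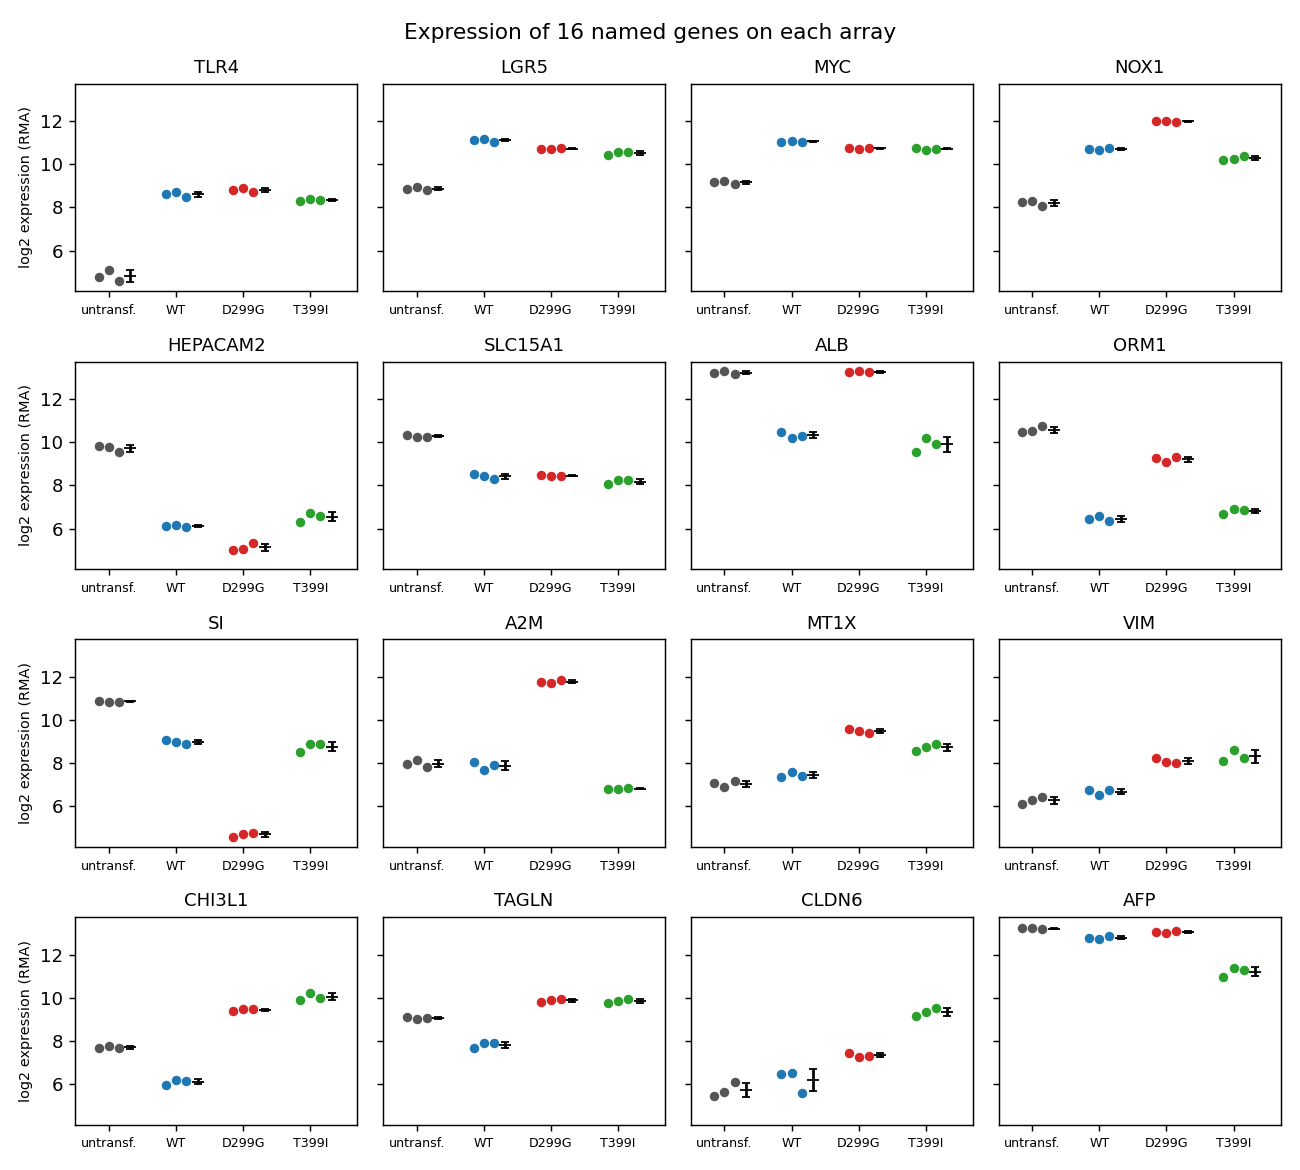
Log2 expression of 16 named genes, with 1 point per array for untransfected cells and for the TLR4-WT, D299G and T399I lines, and a black mark for the mean and SD of 3 arrays. TLR4 rises from 4.83 to between 8.34 and 8.81, SI is lowest in D299G at 4.70, and ALB is at 13.21 in untransfected cells, 13.25 in D299G, 10.31 in WT and 9.89 in T399I.

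The D299G line against the TLR4-WT line compares 2 selected lines, so the substitution is not separated from other differences between them. A2M rose 14.6-fold, from 7.89 ± 0.19 in TLR4-WT to 11.76 ± 0.07 in TLR4-D299G (SD, n = 3, adjusted p = 5.19e-09), beside 7.97 ± 0.17 in untransfected cells. The iron carrier transferrin (TF), UCA1 and the secreted glycoprotein CHI3L1 rose 12.6-fold, 12.1-fold and 10.1-fold, and the drug-metabolising enzymes UGT2B4 and CYP3A5 rose 10.4-fold and 9.96-fold. CLTRN, ODAM, ERP27 and the urothelial protein UPK1B rose 9.04-fold to 9.56-fold. SI fell 19.2-fold and CPS1 8.22-fold, and the glucosidase gene MGAM2, the phosphodiesterases PDE3A and PDE10A, NDNF, SCGN, AASS, GDPD2 and SLC17A4 fell 3.52-fold to 5.91-fold.

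Liver secretory genes rose in D299G against WT (20 of 27 higher and 0 lower, or 22 and 1 adjusted over the list alone, adjusted p = 1.8e-17, and adjusted p = 0.14 with an estimated correlation). C5 rose 7.76-fold, ALB 7.67-fold and ITIH2 6.85-fold. Metallothioneins rose (8 of 8, the same adjusted over the list alone, adjusted p = 1.17e-10, and adjusted p = 0.11 with an estimated correlation), MT1F by 5.59-fold and MT1X by 4.14-fold. Mesenchymal genes rose (11 of 31 higher and 1 lower, the same adjusted over the list alone, adjusted p = 0.000492, and adjusted p = 0.158 with an estimated correlation). TAGLN rose 4.15-fold, TGFB2 3.39-fold, VIM 2.68-fold and CCN1 2.10-fold. In untransfected cells TGFB2 (7.5 to 7.64) was at the level of D299G (7.51 to 7.58). VIM there (6.1 to 6.44) lay below WT (6.55 to 6.74), and TAGLN and CCN1 lay between the lines. Interferon-stimulated genes rose (12 of 33 higher and 0 lower, the same adjusted over the list alone, adjusted p = 0.00235, and adjusted p = 0.181 with an estimated correlation), IFI6 by 2.72-fold. IFI6 was 9.38 to 9.63 in D299G, 7.86 to 8.15 in WT and 9.42 to 9.74 in untransfected cells. Against untransfected cells the interferon list fell in WT (adjusted p = 0.0188) and did not pass in D299G (7 of 33 higher and 9 lower, adjusted p = 0.531). STAT3 pathway genes rose (8 of 21 higher and 0 lower, or 8 and 2 adjusted over the list alone, adjusted p = 0.0198, and adjusted p = 0.155 with an estimated correlation). SERPINA3 rose 2.92-fold, LIFR 2.50-fold and STAT3 itself 1.63-fold. Drug metabolism and NRF2 genes rose (10 of 32 higher and 3 lower, or 11 and 5 adjusted over the list alone, adjusted p = 0.0227, and adjusted p = 0.615 with an estimated correlation), while the estrogen sulfotransferase SULT1E1 fell 2.19-fold. Enterocyte genes fell (6 of 35 higher and 17 lower, or 6 and 18 adjusted over the list alone, adjusted p = 0.00471, and adjusted p = 0.405 with an estimated correlation), although SLC2A2 and CD36 rose 3.63-fold and 3.42-fold. Proliferation genes fell (5 of 40 higher and 17 lower, or 8 and 19 adjusted over the list alone, adjusted p = 0.00759, and adjusted p = 0.627 with an estimated correlation), with MCM6 down 1.43-fold. NUSAP1 fell 1.53-fold and BUB1B 1.39-fold, and both lie in a run of 350 neighbouring genes that was lower in D299G. The STAT3 call was lost on ranks (adjusted p = 0.0504) and among brighter genes (0.0673), and the drug metabolism call in both (0.0715 and 0.0835) and without WT replicate 3 (0.0518). In total 5618 probe sets were called (2615 higher and 3003 lower), of which 439 changed at least 2-fold (302 higher and 137 lower).

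In TLR4-T399I against TLR4-WT, CHI3L1 rose 15.2-fold, from 6.12 ± 0.12 to 10.04 ± 0.16 (SD, n = 3, adjusted p = 5.3e-09), beside 7.70 ± 0.06 in untransfected cells. CST1, CLDN6, TF and NTS rose 13.7-fold, 9.02-fold, 6.33-fold and 6.25-fold, and GABRA3, ACTL8, SULT1C4, PLA2G4A and HSPB8 rose 4.88-fold to 6.09-fold. LYZ fell 3.71-fold, SULT1E1 3.66-fold, GDPD2 3.89-fold and the fetal liver protein AFP 2.97-fold, and the transcriptional coactivator WWTR1 fell 2.57-fold. Lipoprotein genes fell (1 of 24 higher and 13 lower, or 2 and 14 adjusted over the list alone, adjusted p = 4.25e-06, and adjusted p = 0.118 with an estimated correlation), ABCA1 by 1.92-fold. Liver secretory genes fell (5 of 27 higher and 15 lower, or 5 and 17 adjusted over the list alone, adjusted p = 6.32e-06, and adjusted p = 0.409 with an estimated correlation), with AFP and AHSG down and TF up. Proliferation genes rose (16 of 40 higher and 0 lower, or 18 and 1 adjusted over the list alone, adjusted p = 1.78e-06, and adjusted p = 0.455 with an estimated correlation), CENPE by 1.72-fold. Metallothioneins rose (6 of 8, or 7 adjusted over the list alone, adjusted p = 1.84e-08, and adjusted p = 0.11 with an estimated correlation), MT1F by 2.76-fold. Mesenchymal genes rose (9 of 31 higher and 1 lower, or 9 and 2 adjusted over the list alone, adjusted p = 0.0453, and adjusted p = 0.405 with an estimated correlation), TAGLN by 4.07-fold and VIM by 3.10-fold. Drug metabolism genes rose (8 of 32 higher and 2 lower, or 10 and 2 adjusted over the list alone, adjusted p = 0.0212, and adjusted p = 0.615 with an estimated correlation), CYP3A5 by 3.23-fold. The mesenchymal call was lost on ranks (adjusted p = 0.236) and with a replicate block (0.0619). It was also lost without WT replicate 1 or 2, D299G replicate 1, T399I replicate 1, or untransfected replicate 2 or 3 (from 0.0531 to 0.174). The drug metabolism call was lost among brighter genes (0.205) and without T399I replicate 2 (0.162).

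T399I differed from WT at 3456 probe sets (1964 higher and 1492 lower, 56.8% higher), of which 162 changed at least 2-fold (115 higher and 47 lower). With arrays centred on their median the split was 2054 higher and 913 lower (69.2% higher). The count fell to 2194 without WT replicate 1, 2183 without WT replicate 2 and 2119 without T399I replicate 3, the higher part alone to 1288 without WT replicate 3 and 1224 without T399I replicate 2, and was 6084 with array weights and 1945 in a fit of the compared arrays alone. TF, CHI3L1, TAGLN, BAMBI and EXPH5 changed the same way in both mutants against WT, as did 1785 probe sets (1020 higher and 765 lower, and in all 1136 or 1144 without WT replicate 1 or 2, 2875 with array weights and 1144 with only the compared arrays), while 222 changed in opposite directions. With arrays centred 971 were higher and 479 lower in both. Independent lists would share 154, 135 and 294. Across all probe sets the changes of the 2 mutants correlated at r = 0.50, equal to the 0.50 that shared WT arrays gave in simulation, with a covariance of 0.0389 against 0.0101. Part of the excess may come from shared controls, since 3 WT arrays allow no separate controls for each mutant.

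**Figure D3:**
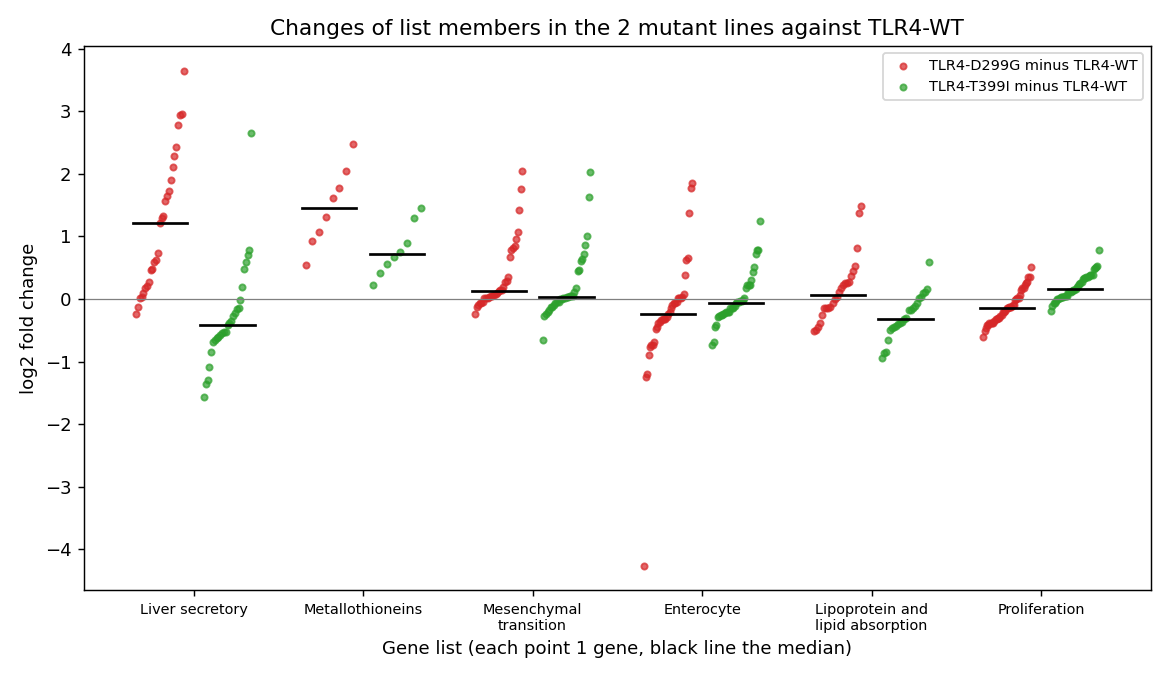
Log2 fold change of each member of 6 gene lists in TLR4-D299G and in TLR4-T399I against TLR4-WT, with 1 point per gene and a black line at the median. Liver secretory genes have a median of 1.22 in D299G and -0.42 in T399I, and metallothioneins 1.46 and 0.72.

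Between the mutants, A2M was 30.8-fold higher in TLR4-D299G than in TLR4-T399I (log2 change 4.94, SE 0.10, n = 3 per group, adjusted p = 1.79e-09). UPK1B, UGT2B10 and ALB were 12.6-fold, 11.1-fold and 10.3-fold higher, SLCO1B3, below the lower quartile in T399I, at least 10.1-fold, and KYNU, an enzyme of tryptophan breakdown, 8.92-fold. SI was 16.6-fold lower in D299G, CPS1 6.29-fold, HOXB9 5.63-fold and the chloride exchanger SLC26A3 4.66-fold. Liver secretory genes were higher in D299G (25 of 27 higher and 0 lower, or 26 and 0 adjusted over the list alone, adjusted p = 1.07e-30, and adjusted p = 0.11 with an estimated correlation). Lipoprotein genes were higher (13 of 24 higher and 3 lower, the same adjusted over the list alone, adjusted p = 5.19e-05, and adjusted p = 0.14 with an estimated correlation), APOC3 by 4.71-fold. Metallothioneins were higher (6 of 8, or 8 adjusted over the list alone, adjusted p = 1.82e-06, and adjusted p = 0.14 with an estimated correlation). STAT3 pathway genes were higher (8 of 21 higher and 1 lower, or 10 and 1 adjusted over the list alone, adjusted p = 0.00166, and adjusted p = 0.11 with an estimated correlation), SERPINA3 by 4.40-fold and FGL1 by 3.77-fold. Interferon-stimulated genes were higher (7 of 33 higher and 0 lower, the same adjusted over the list alone, adjusted p = 0.0227, and adjusted p = 0.298 with an estimated correlation), as were mesenchymal genes (6 of 31 higher and 2 lower, the same adjusted over the list alone, adjusted p = 0.0249, and adjusted p = 0.345 with an estimated correlation). Proliferation genes were lower (0 of 40 higher and 25 lower, or 31 lower adjusted over the list alone, adjusted p = 2.59e-13, and adjusted p = 0.262 with an estimated correlation). MKI67 was 1.72-fold lower and KIF23, which lies in the same run of neighbouring genes, 1.60-fold. Enterocyte genes were lower (6 of 35 higher and 16 lower, or 6 and 17 adjusted over the list alone, adjusted p = 0.00122, and adjusted p = 0.342 with an estimated correlation), with CA12, also in that run, down 2.76-fold. The interferon call was lost without D299G replicate 1 (adjusted p = 0.0517) or T399I replicate 1 (0.105), and the mesenchymal call without D299G replicate 1 (0.0529) and among brighter genes (0.0889). In total 4476 probe sets were called (1933 higher and 2543 lower), of which 323 changed at least 2-fold (202 higher and 121 lower). Array weights gave 7555.

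Each line also had genes that set it apart from all 3 other groups. In D299G these were led by A2M, UPK1B, SLCO1B3, UCA1, CLTRN, UGT2B4, the cytokine receptor chain IL2RG and fibrinogen FGA on the high side, each at least 3.92-fold higher than in every other group. On its low side stood SI (16.6-fold or more), CPS1, the ion transporters SLC26A3 and CFTR, NDNF, PLXDC2, KLHL8 and TLN2, the last of which lies in the run of neighbouring genes. Named genes were looked up in that run only, so the other genes may lie in other shifted blocks. Against T399I, the blocks from GPR22 to RNF133 and from BMP3 to GPRIN3 also had lower medians in D299G (log2 change -0.23 and -0.3). T399I stood apart by high CLDN6, the actin-severing protein SCIN, CST1, the fatty acid desaturase FADS2, the pluripotency factor LIN28A, GABRA3, TLL1 and ITGB8, each at least 2.43-fold. It stood apart by low AFP, KYNU, SERPIND1, AHSG, UGT2A3, A2M, SERPINA6 and F2, each at least 2.04-fold. TLR4-WT had high GDPD2, AASS, SULT1E1, CEACAM6, CP, RPL22L1, SLC6A6 and CCDC183, and low EXPH5, CHI3L1, BAMBI, TF, FAM171B, CFI, ITPR2 and FABP3. The counts set apart were 1752 probe sets in D299G (657 higher and 1095 lower), 714 in T399I (360 higher and 354 lower, 50.4% higher), 967 in WT (330 higher and 637 lower, 34.1% higher) and 5238 in untransfected cells. At 2-fold or more the balance in D299G turned to 68 higher and 28 lower, with 17 and 14 in T399I and 4 and 29 in WT. With arrays centred on their median they were 346 higher and 222 lower in T399I (60.9% higher), and 186 higher and 628 lower in WT (22.9% higher). The balance in T399I turned on single arrays, with 482 higher and 284 lower without T399I replicate 1, 179 and 312 without replicate 2, and 169 and 239 without replicate 3. The T399I count fell to 473 without WT replicate 2 and 408 without T399I replicate 3, and the WT count to 644 without WT replicate 1. The higher part of the WT count fell to 208 without WT replicate 1 and 190 without WT replicate 2. Array weights gave 1295 for T399I, and fits of only the compared arrays 353 for T399I and 600 for WT.

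TLR4 signalling genes did not pass as a list, and 10 of the 23 lists were not called in any of the 7 comparisons. In the mean of the lines, 4 of 26 members of the TLR4 list were higher and 10 lower (4 and 11 adjusted over the list alone, adjusted p = 0.203). That list had a median log2 change of -0.14, a mean of 0.03, which TLR4 itself raises, and a test direction of lower. NF-kB targets had 11 of 28 higher and 3 lower (adjusted p = 0.454), and CCL20 and PTGS2 were highest in D299G, at 8.83 ± 0.13 and 7.46 ± 0.13 (SD, n = 3) against 6.15 ± 0.12 and 5.26 ± 0.30 in untransfected cells. In D299G against WT the NF-kB list would be called among brighter genes (adjusted p = 0.0403) and without WT replicate 1 (0.046) or D299G replicate 3 (0.0492). Junction and keratin genes had 10 of 28 higher and 9 lower (adjusted p = 0.996, with a median of -0.01 and a mean of 0.04 around a test direction of lower), laminin, integrin and matrix genes 10 of 29 higher and 8 lower (adjusted p = 0.705), and apoptosis and p53 targets 10 of 24 higher and 9 lower (adjusted p = 0.981, with a median of 0.15 against a test direction of lower). Cholesterol synthesis genes had 2 of 20 higher and 7 lower (3 and 7 adjusted over the list alone, adjusted p = 0.326), and goblet and Paneth markers 10 of 24 higher and 5 lower (adjusted p = 0.322), although in T399I against WT that list would be called among brighter genes (0.0224). Enteroendocrine markers had 7 of 21 higher and 2 lower (adjusted p = 0.275), fibroblast markers 5 of 17 higher and 2 lower (adjusted p = 0.497), and leukocyte markers 8 of 20 higher and 2 lower (adjusted p = 0.17). Hypoxia and glycolysis genes would be called lower in T399I against WT (adjusted p = 0.052) among brighter genes (0.0285), with the mean of probe sets (0.0485) and without WT replicate 3 (0.0224) or T399I replicate 1 (0.0381) or 2 (0.0496). In the mean of the lines they (0.0567) would be called higher among brighter genes (0.0428) and without WT replicate 3 (0.0466) or untransfected replicate 2 (0.0255). Proliferation genes there (0.0937) would be called higher among brighter genes (0.0429) and without T399I replicate 1 (0.0492) or untransfected replicate 2 (0.018). LYZ stands on both the Paneth and the leukocyte list, and CD14 on both the TLR4 and the leukocyte list. Drug metabolism genes in the mean of the lines had a median of 0.03, a mean of -0.07 and a test direction of lower (adjusted p = 0.702).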

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

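The limit of 2-fold for opposite effects was set after a longer list had been seen. The tests on the amount of TLR4 transcript and on copy number in runs of neighbouring genes were also chosen only after the result was seen, as was the count shared by both mutants.

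Several genes changed at least 2-fold in opposite directions in 2 lines against untransfected cells. The difference between those lines follows from that choice, so its test adds no support. The iron carrier TF fell in TLR4-WT (log2 change -1.58) and rose in D299G (2.08) and T399I (1.09), which differed from WT by 3.65 and 2.66 (adjusted p = 3.72e-07 and 1.13e-05). CHI3L1 fell in TLR4-WT by 1.58 and rose by 1.75 in D299G and 2.34 in T399I, with differences from WT of 3.33 and 3.92 (adjusted p = 5.19e-09 and 5.3e-09). The small heat shock protein gene HSPB8 differed from WT by 2.60 in D299G and 2.29 in T399I (adjusted p = 6.9e-07 and 6.21e-06). FABP3 (2.95), UGT2B4 (3.38), CYP3A5 (3.32), ERP27 (3.18) and UGT2B10 (3.08) fell in WT, rose in D299G and differed between these lines by the log2 values in brackets. A2M rose in D299G (3.79) and fell in T399I (-1.16), a difference of 4.94. ERP27 (2.31) and UGT2B10 (3.47) were likewise higher in D299G than in T399I, and PLXDC2 (-2.26) was lower. UGT2B4 and UGT2B10 belong to a family of near-identical genes, so a probe set of one can report another. Over all probe sets, called effects were opposite at 351 between WT and D299G, 137 between WT and T399I, and 248 between D299G and T399I, and both at least 2-fold at 11, 3 and 6.

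Both mutant lines differed from TLR4-WT at 1785 probe sets in the same direction. The amount of TLR4 transcript, with the highest mean in D299G and the lowest in T399I, would move the mutants apart, although neither mutant passed the test against WT. The covariance of their changes was 0.0389, above the 0.0101 (0.00964 to 0.0107) that shared WT arrays gave in simulation. That simulation held only the noise between arrays. A trait of the WT line itself would also raise the covariance, so the comparison does not decide on the amount of TLR4. Some blocks of neighbouring genes had such a pattern. From SPATA45 to DNAH14 the median log2 change was -0.53 in WT against untransfected cells, and 0.34 (D299G) and 0.31 (T399I) against WT. From SLC25A5 to STK26 the mutants themselves were lower, at -0.33 and -0.28 against WT and -0.51 and -0.38 against untransfected cells. Of the 2007 probe sets called in both, 88.9% moved the same way, a share that the shared arrays raise and that decides nothing alone, since over all probe sets it was 65.1% against 66.6% in simulation. At most 16.3% of called genes, against 8.68% of all genes placed in blocks, lay in shifted blocks of 50 neighbours (D299G against WT). That share does not decide on chromosome copy number as a whole, since block medians can miss shorter gains or losses. They also count genes with low values. In the run from THBS1 to FAH, the median log2 change in D299G against WT was -0.28 over all genes and -0.51 over the brighter ones. In shifted runs, 76.5% of even-numbered genes (95% interval 71.3 to 81.2%) moved the way of the odd-numbered genes of their block in D299G against WT. For those runs copy number may account for the shift, with regional regulation not excluded. The TLR4 variant itself, as the biological alternative, stays open and untested, because the labels do not show more than 1 clone of any variant.

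SI was lower in TLR4-D299G than in the other 3 groups. One outlying array is argued against, since the smallest log2 change from WT without 1 D299G array was -4.21. The loss was not of SI alone, since 17 of the 23 called enterocyte genes were lower in D299G than in WT, while SLC2A2 and CD36 were higher. At 73.9% (95% interval 51.6 to 89.8%, around the 75% set before the result was seen), lower enterocyte differentiation as a whole and a change in part of it cannot be told apart. The D299G variant, as the biological alternative, is untested.

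The 3 TLR4 lines shared changes at 5238 probe sets against untransfected cells. Signalling through NF-kB in every line did not meet its prediction as the common source. Of 28 NF-kB targets, 6 (PTGS2, ICAM1, RELB, CCL20, CXCL1 and LCN2) were higher in all 3 lines, a minority where a majority was predicted before the result was seen. SOD2 and CFB were lower. That share still lies above the 1715 of 18417 over all genes, and fry called the list higher in the mean of the lines (adjusted p = 0.000918). A part of NF-kB thus stays open. Effects of transfection, selection with blasticidin or choice of clone cannot be told apart from those of TLR4, since 0 of the 12 arrays came from an empty-vector line. Overexpressed TLR4, as the biological alternative, thus stays open for genes such as LGR5, MYC and SLC15A1.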

How the results depend on the processing

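All alternatives for the count shared by both mutants were tests chosen only after the result was seen. P-values measure only the spread between these samples, which may be technical, and without detection calls the lower limit of signal over background is not known. Of 391 named gene results, 7745 of 7765 alternatives kept the call, or its absence for TLR4 in either mutant against WT. In 20 the gene was no longer past the threshold, and 0 reversed. The 20 all came from leaving out 1 array and concerned CENPE and HP in D299G against WT, HP in T399I against untransfected cells, and MX1, SAMD9 and TLR4 between the mutants. Of 161 list results, 45 were called and 116 were not. Of their 2898 alternatives, 2734 left that status unchanged, 79 lost a call, 85 gained one and 0 reversed. The 2734 include lists that stayed uncalled. With an estimated correlation 45 list calls were lost, which left 0, 0, 0, 0, 0, 0 and 0 in the order of comparisons below. Fry gave 17, 15, 18, 16, 15, 15 and 18 lists, and ranks left 3 lists for the mean of the lines.

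Counts within 1.5 times came from the variance prior, the brighter probe sets, those with 1 symbol, centring and quantiles. Array weights, in which T399I replicate 3 counted most (2.47) and untransfected replicate 3 least (0.415), gave 6084 for T399I against WT, 7555 between the mutants, 1295 set apart in T399I and 2875 shared by both mutants. Only the compared arrays, with fewer degrees of freedom, gave 6508 for T399I against untransfected cells, 1945 for T399I against WT, 353 set apart in T399I, 600 in WT and 1144 shared by both mutants. In the order WT, D299G and T399I against untransfected cells, D299G and T399I against WT, D299G against T399I, and the mean of the lines, a change of at least 2-fold left 659, 1009, 763, 439, 162, 323 and 594. It left 96 set apart in D299G, 31 in T399I, 33 in WT and 218 in untransfected cells, 218 shared by the 3 lines and 86 by both mutants. An adjusted p under 0.01 left 6157, 7172, 6058, 3446, 1630, 2580 and 8256, and 9222 for any difference. It left 987, 294, 458 and 2907 set apart, 2907 shared by the 3 lines and 849 by both mutants.

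Without each array in turn the ranges were 7557 to 11095, 9199 to 12498, 7982 to 9904, 4161 to 5905, 2119 to 3711, 3136 to 4847 and 9795 to 13592, and 11930 to 14566 for any difference. Sets apart ranged from 1241 to 1834 in D299G, 408 to 766 in T399I, 644 to 995 in WT and 3949 to 5733 in untransfected cells, which is also the range for the 3 lines, and both mutants shared 1136 to 1891. Moves over 1.5 times came without WT replicate 1 (T399I against WT 2194, WT apart 644, both mutants 1136), WT replicate 2 (2183 for T399I against WT, 473 for T399I apart, 1144 for both mutants) and T399I replicate 3 (2119 and 408). Lists ranged from 6 to 6, 5 to 5, 6 to 7, 7 to 9, 5 to 7, 6 to 8 and 5 to 7.

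Replicate numbers may pair the arrays in part. Of 18 pairs with the same number, deviations from the group means correlated at r from -0.08 to 0.27, with 5 over 0.1. Replicate 2 gave r = 0.244 between WT and T399I and 0.274 between T399I and untransfected cells, but -0.079 between WT and D299G. In all, 8 of 12 arrays correlated best with their own number, so a batch by number is not excluded. With the replicate number as a block the counts were 11019, 12335, 10173, 5733, 3465, 4632 and 13615, and 14387 for any difference. Set apart were 1840, 738, 980 and 5544, and both mutants shared 1777. The block gave 6, 5, 6, 8, 5, 8 and 5 lists, without mesenchymal genes in T399I against WT (adjusted p = 0.0619) and MHC class I genes in the mean of the lines (0.058).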

Other observations

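The genes of the next 2 paragraphs, the ERK tests and the count of neighbouring genes in the run from THBS1 to FAH were chosen only after the result was seen, as was the size below which chromosomes were left out of the blocks.

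TFF3 and TFF2, trefoil peptides that goblet and mucous cells secrete, were lower in both mutants than in TLR4-WT, although the goblet and Paneth list was not called (adjusted p = 0.661 in D299G and 0.259 in T399I). TFF3 had log2 values of 10.16 in WT, 8.98 in D299G and 9.35 in T399I (log2 changes -1.18 and -0.81, adjusted p = 1.88e-06 and 8.52e-05). TFF2 fell by 1.59 and 1.21 (adjusted p = 2.88e-06 and 5.98e-05). PLA2G2A, a secreted antibacterial phospholipase of Paneth cells, fell by 1.75 in WT against untransfected cells (adjusted p = 2.82e-07) and was 2.57 higher in D299G than in WT (adjusted p = 3.01e-08). The chemokine CCL20 and the prostaglandin synthase PTGS2 were 1.80 and 1.77 higher in D299G than in WT (adjusted p = 2.11e-06 and 9.16e-06).

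In the mean of the 3 lines, the efflux pumps ABCB1 and ABCG2 rose by 1.21 and 1.39 (adjusted p = 3.65e-07 and 1.4e-06), the pore-forming claudin CLDN2 by 1.12 (adjusted p = 1.01e-06) and CEACAM1 by 1.15 (adjusted p = 4.75e-07). SCG5, a chaperone of neuroendocrine cells, fell by 1.30 (adjusted p = 1.36e-06).

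DUSP6, which ERK signalling induces, rose in each line, and higher output of the ERK pathway in every line is a hypothesis from that rise. Of 9 other ERK output genes, 6 (EPHA2, PHLDA1, SPRY2, ETV4, ETV5 and SPRY4) were higher in all 3 lines and 0 were lower in all 3. CCND1, EPHA4 and DUSP4 were not higher in all 3. CCND1 did not pass in D299G (log2 change 0.09, adjusted p = 0.318), nor DUSP4 in WT (0.13, adjusted p = 0.366). EPHA4 was called lower in WT (-0.26, adjusted p = 0.0335) and higher in T399I (0.61, adjusted p = 0.000252). The pattern is consistent with higher ERK output, although no phosphorylated protein was analysed here and the genes were listed after DUSP6 and CCND1 had been seen.

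A run of 350 neighbouring genes from THBS1 to FAH was lower in TLR4-D299G. Against WT, 170 of these genes were called lower and 10 higher, and among the 203 brighter ones the median log2 change was -0.51, with 93.6% lower. Against untransfected cells the brighter genes had a median of -0.55 and against T399I -0.47, while the 3 comparisons without D299G gave -0.08, -0.05 and -0.03. The run holds THBS1, BUB1B, NUSAP1, TLN2, CA12, KIF23 and CYP1A1, of which THBS1 and CYP1A1 were nevertheless higher in D299G or T399I than in WT. In all, 31 of 356 blocks passed the limit set by random orders in D299G against WT (13 higher and 18 lower), 17 in T399I against WT and 26 between the mutants. Loss of a copy of this stretch in the D299G line may explain the run. The 76.5% of even-numbered genes that moved the way of their block covers 12 blocks over the genome and is no value for this run.

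Other splits of the samples were counted for each result, with real value and highest other given in that order. Comparisons of 3 with 3 arrays allow 10 splits, too few for a share under 0.05. For probe sets, 1 of the 10 splits reached the real count in each: 10404 and 0 for WT, 11785 and 0 for D299G and 9806 and 0 for T399I against untransfected cells, 5618 and 0 for D299G and 3456 and 2 for T399I against WT, and 4476 and 0 between the mutants. For lists the real and highest other counts were 6 and 5, 5 and 5, 6 and 5, 8 and 5, 6 and 5, and 8 and 8, reached by 1, 2, 1, 1, 1 and 2 of 10 splits.

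The splits move single arrays and not whole lines, so they cannot tell whether further clones of a construct would differ as much. With 9 and 3 arrays, 1 of 100 splits reached the 13064 probe sets of the mean of the lines (highest other 1692). A chance division of these arrays is argued against there. For its 6 lists such a division is not excluded, since 12 of 100 splits reached them (highest other 9). With 4 groups of 3, it is argued against for any difference (1 of 100, 13962 and 5176), D299G apart (1, 1752 and 571) and WT apart (1, 967 and 428). The same holds for untransfected cells apart (1, 5238 and 3458) and both mutants shared (1, 1785 and 593). Probe sets shared by the 3 lines are by definition those set apart in untransfected cells, so they add no separate result. For T399I apart (2 of 100, 714 and 3360) no conclusion is drawn, since the split with 3360, several times the real count, points to a structure of the samples.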
